A study of Rhodobacter capsulatus DE442 and Rhodobacter capsulatus SB 1003 with 18 samples.

How the data were processed

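Cultures of Rhodobacter capsulatus SB1003 and DE442 were started at 20 Klett units in anaerobic phototrophic tubes and grown for 15 to 16 hours to early stationary phase, per the labels' protocols. Extraction followed a kit protocol for the small RNA fraction, so the share of long RNAs depends on that step. End libraries followed a protocol based on differential RNA sequencing, with and without TEX, and total RNA libraries an Ion Torrent kit, per the labels. The 18 libraries comprised 2 for each combination of strain, end and TEX treatment and 1 total RNA library per strain. Nothing in the labels says whether replicate libraries came from separate cultures.

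The 6 deposited files hold 3 lists per strain, each pooled over that strain's libraries. Aligner, caller, thresholds and genome build are not given in the sources used here. TSS and TTS lists carry a log2 value deposited by the authors whose definition is not stated. Every TSS value was 0.251 or more and every TTS value -0.235 or less, and ends were ranked within a list by the size of the value, with no meaning given to its sign. Some neighbouring TSSs carry the same log2 value, so values can come from a window. Transcript lists carry a signal deposited by the authors, called level here, and a fraction deposited by the authors between 0.7 and 1.0 whose meaning is not stated and which was used only as a filter. The level was read as mean read depth along the transcript without normalization: level times length came out whole, within the rounding of 3 decimals, for 52.3% of SB1003 and 51.3% of DE442 transcripts under 150 nt, against 10.7% and 10.4% by chance. This reading is an inference from the values. It was reached after trying 5 offsets of the length, and it does not hold for every transcript. Which libraries enter the level is not stated, so ratios of level between strains also carry any difference in depth.

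Gene-based results planned before the data were examined were not computed, because the annotation at hand is of a contig assembly whose coordinates cannot be tied to the files. TSS classes by gene, 5' leader lengths, gene-based operons, gene lists, named genes and sequence at ends are thus not analysed here, and no gene name was inferred from a position. Their substitutes were chosen after the data had been seen: units of overlapping transcripts, TSS position within a unit with a limit of 50 nt, log2 classes, loci joined over strains, levels at loci with at least 3 shared transcripts, repeat loci and depth steps. The regions named are the top 5 units per strain by transcripts and by length, the 5 TSSs with the most transcripts, the 5 TSSs and TTSs of largest log2 size, the 5 longest stretches covered in 1 strain, and the 5 loci at either extreme of TSS difference and of level, of which the text gives a selection made after their values were seen. Naming the 5 top ends was planned; the other region rules follow the planned gene rules in form.

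Positions were counted from 1. Planned comparisons were the overlap of TSSs within 5 nt, of TTSs within 10 nt and of transcripts with both ends within 10 nt, on the same strand, and the match of transcript ends to listed ends within 10 nt. Chance overlap over the whole span came from 1000 random circular shifts, which do not keep shared transcribed regions aligned. The span was taken as the last position in the files, 3738899. Intervals are exact (Clopper-Pearson) 95% binomial intervals. No test between strains was made, since there is 1 list per strain. Levels were centred on the median log2 ratio of shared transcripts outside the repeat loci. Repeat loci hold at least 5 transcripts with the length and level of another transcript at least 10 kb away, at levels of 10 or more. Depth steps compared mean depth on either side of an end, derived from nested transcripts of fraction 1.0 with flanks of at least 20 nt and a floor of 3. The same subtraction, without the limits on fraction, flanks and floor, gave the highest DE442 depth allowed in the stretch of an SB1003 transcript in a repeat locus. All DE442 depth after the earlier part of the locus was put into that stretch.

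Functions were tested on simulated data. For TSSs, a copy of the 4045 SB1003 positions with 40.5% moved within 5 nt and the rest placed at random gave 40.9% shared. For transcripts, 25.3% simulated gave 25.3% of 14440. All 1000 simulated units were recovered. An early form of the depth step, which took the median over every pair of flanks, understated a simulated 4-fold step, and the shortest flanks were used instead. These gave a median log2 of 2.00 for a simulated log2 of 2.00 at 500 TSSs. Simulated levels were exact mean depths, so this check does not test whether the deposited level is mean depth. Alternatives covered distances, the better-ranked part of each list, filters and joining rules. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.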

Results

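The purple photosynthetic bacterium Rhodobacter capsulatus was examined in 2 strains, SB1003, a widely used laboratory strain, and DE442, known as an overproducer of gene transfer agents, which are phage-like particles that carry pieces of the host chromosome. Each strain had 9 libraries from early stationary, anaerobic photosynthetic cultures: 2 each of 5' end and 3' end libraries with and without terminator exonuclease (TEX), an enzyme that degrades RNA with a 5' monophosphate and leaves RNA with a 5' triphosphate, and 1 total RNA library. The deposited values are 1 list of transcription start sites (TSSs), 1 of transcript 3' ends (TTSs) and 1 of transcripts per strain, each pooled over libraries. No value per library was used here and the sequencing depth is unknown, so differences between the strains have no replicate check and carry no p-value. Positions are those of the sequence named Chromosome in the files, whose build is not given in the sources used here, and genes were therefore not named. Intervals are exact 95% binomial intervals over listed positions, units or transcripts taken as independent, and cover counting error only.

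The study asked how complex the transcription units of this organism are. SB1003 had 4045 TSSs, 2906 TTSs and 14440 transcripts, and DE442 had 5374, 3279 and 24195. The ratio of DE442 to SB1003 was thus 1.33 for TSSs, 1.13 for TTSs and 1.68 for transcripts. Median transcript length was 420 nt in SB1003 and 668 nt in DE442. This median counts each combination of a TSS and an end, so units with many ends weigh more in it. The 2 DE442 loci of many TSSs described below held 560 SB1003 and 5000 DE442 transcripts. Units of overlapping transcripts, also described below, had median lengths of 334.5 and 340 nt. Removing the repeat loci described below raised the transcript ratio to 1.85, because SB1003 had 1771 transcripts there and DE442 812.

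The lists were first compared for positions found in both strains. Of the SB1003 TSSs, 1556 (38.5%, interval 37.0 to 39.99) had a DE442 TSS within 5 nt on the same strand, and of the DE442 TSSs 1819 (33.8%, 32.6 to 35.1) had one in SB1003. Randomly shifted lists gave means of 0.63% and 0.51%. The shifts also break the alignment of regions transcribed in both strains, so they do not give the chance level within such regions. The TSS of SB1003 with the highest deposited log2 value, 56824 on the plus strand at 8.12, had a DE442 TSS 1 nt away at 5.42, and the TSS at 88835 on the minus strand was at the same position in both, at 7.91 in SB1003 and 6.81 in DE442. The highest DE442 TSS, 2651374 on the plus strand, was at 8.19, while the SB1003 TSS 3 nt away was at 1.66. The DE442 TSS at 2971490 on the plus strand, at 8.03, had no SB1003 TSS closer than 157 nt. TSSs at the same position in both lists numbered 859, and their log2 values had a Spearman correlation of 0.80 across positions, which are not independent replicates. Joining neighbouring TSSs within 5 nt, a choice made after the data were seen, left 33.3% of SB1003 and 26.9% of DE442 TSSs shared.

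The shared percentage was higher in classes of larger log2 value in both strains. Among SB1003 TSSs under 0.5 it was 21.5% (19.1 to 24.0, n = 1120), and over 4 it was 77.1% (72.0 to 81.7, n = 310). In DE442 it was 18.1% (16.2 to 20.0, n = 1673) under 0.5 and 80.3% (75.5 to 84.5, n = 320) over 4.

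**Figure D1:**
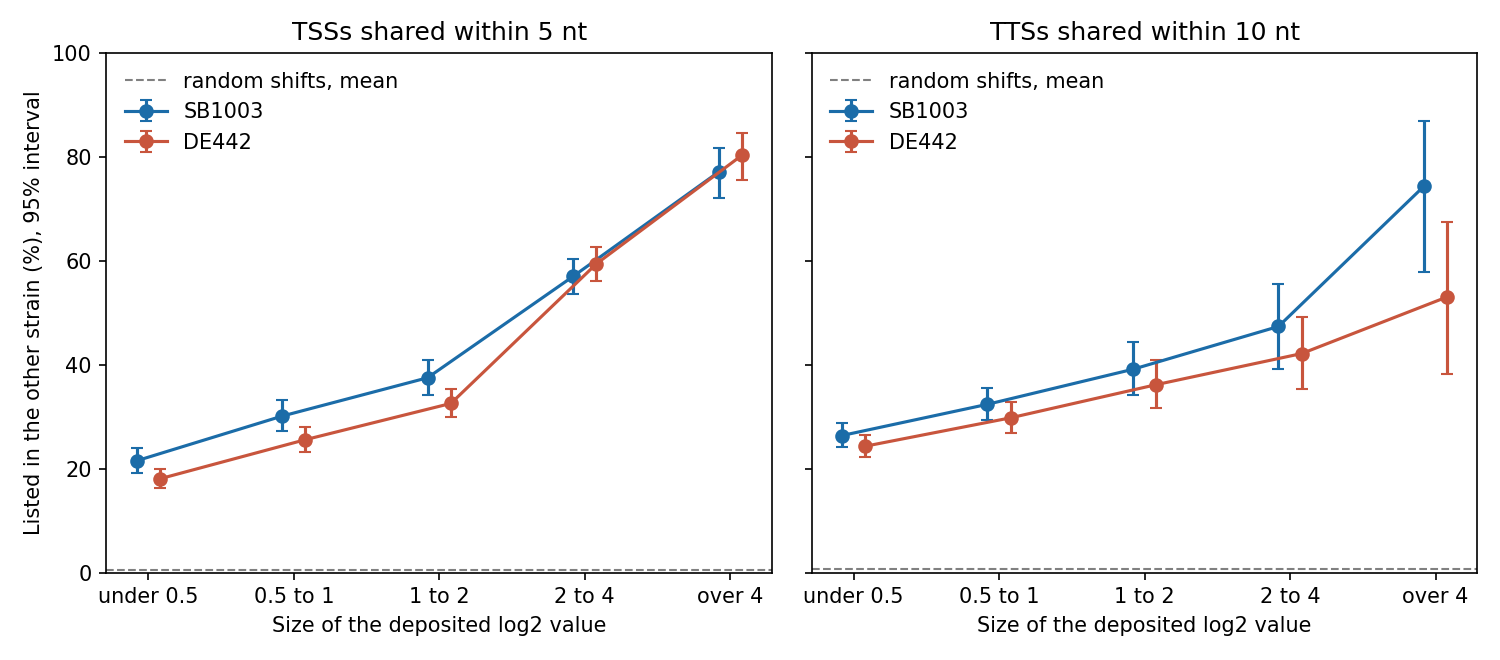
Percentage of TSSs (left, within 5 nt) and TTSs (right, within 10 nt) listed in the other strain on the y axis, by size of the deposited log2 value on the x axis; points are pooled lists of SB1003 and DE442, bars are exact 95% binomial intervals and the dashed line is the mean of random shifts. Shared TSSs go from 21.5% to 77.1% in SB1003 and from 18.1% to 80.3% in DE442 between the lowest and the highest class.

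For 3' ends, 917 SB1003 TTSs (31.6%, 29.9 to 33.3) and 948 DE442 TTSs (28.9%, 27.4 to 30.5) had a counterpart within 10 nt, against 0.77% and 0.70% in shifted lists. The definition of the log2 value is not stated, and TTSs, which are all negative, were ranked by its size alone. The TTS of largest size in both strains was the same position, 1519425 on the plus strand, with a log2 value of -10.61 in SB1003 and -11.03 in DE442. This position lies within a repeat locus described below, 1513758 to 1519569. It is therefore open whether its signal comes from that copy alone. The next in size had no close counterpart: the SB1003 TTSs at 3576773 on the minus strand and 165670 on the plus strand, both at -8.90, had their nearest DE442 TTS at offsets of -4528 and -3973 nt, and the DE442 TTS at 3190825 on the minus strand, at -9.28, had its nearest SB1003 TTS at 2477 nt. These 2 SB1003 TTSs carry an identical value and lie in stretches next to copies of the repeat family described below, so it is open whether they are ends of separate copies. TTSs at 2904402 and 2132904 on the plus strand coincided, at -8.63 and -8.83 in SB1003 and -8.20 and -6.63 in DE442. The DE442 TTS at 2651461 on the plus strand, at -8.83, lies just after the highest DE442 TSS, and the nearest SB1003 TTS was at an offset of -1726 nt. Above a size of 4 the shared percentage was 74.4% (57.9 to 87.0, n = 39) in SB1003 and 53.1% (38.3 to 67.5, n = 49) in DE442. These percentages depend on the distance allowed, and only 196 TTSs had identical positions.

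Transcripts join the listed ends. Every transcript of both strains began at a listed TSS, and 86.4% of SB1003 and 91.3% of DE442 transcripts ended within 10 nt of a listed TTS. Transcripts that ended exactly at a TTS had a median level of 167 in SB1003 and 215 in DE442, and those that ended elsewhere 15.0 and 13.3. Most TSSs began more than 1 transcript, 63.5% in SB1003 and 66.7% in DE442. The TSS with the most transcripts in SB1003, 3627685 on the plus strand, began 33, from 178 to 8187 nt long. In DE442 the TSS at 755175 on the plus strand began 50, from 151 to 12483 nt long. The units of overlapping transcripts that hold these TSSs had 33 and 50 ends, the same numbers. These counts thus follow the number of ends and are not counts of separately observed RNAs. Transcripts with both ends within 10 nt in the other strain made up 22.7% (22.0 to 23.4) of the SB1003 list and 18.1% (17.6 to 18.6) of the DE442 list. Many transcripts share an end, so these intervals, which take them as independent, are too narrow. Allowing 50 nt raised the shared percentages to 43.6% and 33.9%.

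Overlapping transcripts of the same strand were joined into units, which stood in for the planned gene-based operons. SB1003 had 2044 units and DE442 2155, with median lengths of 334.5 and 340 nt. Units with 1 TSS and 1 end made up 48.4% (46.2 to 50.6) in SB1003 and 48.4% (46.2 to 50.5) in DE442. Units with several TSSs and several ends made up 28.2% (26.2 to 30.2) and 32.0% (30.01 to 34.0). The mean number of TSSs per unit was 1.98 in SB1003 and 2.49 in DE442, and that of ends 2.41 and 2.50. Units of more than 100 transcripts numbered 15 in SB1003, holding 27.9% of its transcripts, and 36 in DE442, holding 48.9%. An end here is any transcript 3' end, whether listed as a TTS or not. Of the TSSs, 26.2% in SB1003 and 21.4% in DE442 began no transcript that ended exactly at a TTS. Only transcripts with both ends listed left 1034 and 1082 units. Of these, units with several TSSs and several ends made up 42.6% and 48.2%, so the percentages by class depend on which ends are counted.

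The unit with the most transcripts was a 12483-nt stretch of DE442 at 755175 to 767657 on the plus strand, with 3507 transcripts, 123 TSSs and 50 ends. In SB1003 the same stretch held 5 units, 47 TSSs and 427 transcripts. The next, 1969972 to 1981866 on the minus strand of DE442, had 1493 transcripts and 70 TSSs, against 4 units, 20 TSSs and 133 transcripts in SB1003. These 2 loci had the greatest excess of TSSs in DE442 and held 45.5% of the difference of 9755 transcripts between the lists. Further DE442 units lay at 722065 to 729261 on the minus strand, with 609 transcripts against 372 in SB1003, and at 1110924 to 1115279 on the minus strand, with 561 against 126. The order was the opposite at 3627685 to 3635871 on the plus strand, the unit with the most transcripts in SB1003: it had 553 transcripts from 26 TSSs, against 201 transcripts and 25 TSSs in DE442. The longest SB1003 unit, 326535 to 335131 on the plus strand, had 46 transcripts against 16 in DE442.

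**Figure D2:**
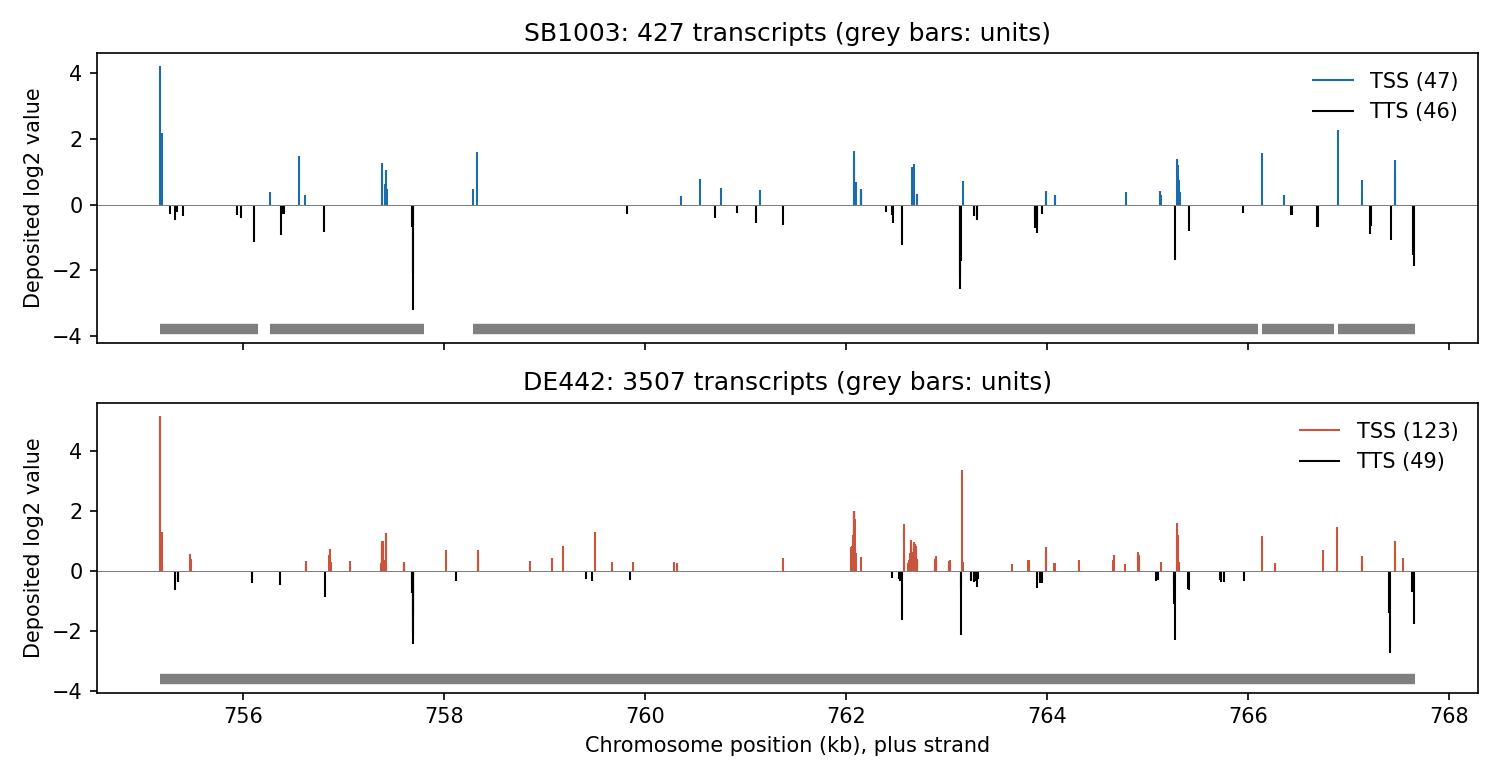
Deposited log2 values of TSSs (coloured, above 0) and TTSs (black, below 0) on the y axis against chromosome position in kb on the x axis, for the plus strand from 755175 to 767657 in SB1003 (top) and DE442 (bottom); grey bars are units of overlapping transcripts. SB1003 has 47 TSSs in 5 units and DE442 has 123 TSSs in 1 unit.

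TSSs were then placed within their units. The first TSS of a unit accounted for 50.5% (49.0 to 52.1) of SB1003 and 40.1% (38.8 to 41.4) of DE442 TSSs. TSSs more than 50 nt after the first made up 32.3% (30.8 to 33.7) and 41.0% (39.7 to 42.3). Their median log2 value was 0.48 in each strain, against 1.54 and 1.38 for first TSSs. TSSs 1 to 50 nt after the first were shared most often, at 59.1% (55.3 to 62.7) in SB1003 and 54.9% (51.7 to 58.0) in DE442. They lie near another TSS by definition, so several can match the same TSS of the other strain. First TSSs were shared at 34.5% and 31.0%, and TSSs more than 50 nt after the first at 33.7% and 27.0%, despite their different log2 values. TSSs inside a unit of the other strand made up 3.02% (2.51 to 3.59) in SB1003 and 2.34% (1.96 to 2.79) in DE442. Units covered both strands over 0.41% of the 3738899-nt span in SB1003 and 0.36% in DE442, below the 2.59% and 3.40% that independent placement of the strands would give.

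Transcripts covered 31.8% of the span on either strand in SB1003 and 36.6% in DE442, and 76.0% of the SB1003 coverage lay within DE442 coverage of the same strand. Stretches of 1 kb or more covered in 1 strain numbered 31 in SB1003 and 61 in DE442. The longest was 3726843 to 3730056 on the minus strand of SB1003, 3214 nt with 7 TSSs and a level up to 795. Another SB1003 stretch, 326535 to 329216 on the plus strand, included a TSS of log2 value 5.29. The longest DE442 stretch, 1659382 to 1661759 on the plus strand, was 2378 nt long and had a level up to 65.3, and that at 791273 to 793466 on the plus strand had a level up to 237. When transcripts of both strains were joined, 1262 loci were found in both, 600 in SB1003 alone and 835 in DE442 alone. Of the 1262, DE442 had more TSSs in 433, as many in 571 and fewer in 258. The excess at 219691 to 222710 on the minus strand was 31 against 8, and at 2516816 to 2516916 on the minus strand SB1003 had 14 against 1.

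Levels were compared at the 3277 SB1003 transcripts with both ends shared. Outside the repeat loci, 3019 transcripts had a median log2 ratio of DE442 to SB1003 of -0.031 and a Spearman correlation of 0.88 across transcripts, which overlap and are not replicates. Relative to that median, 42 of 217 loci with at least 3 shared transcripts were more than 2-fold higher in DE442, 31 were more than 2-fold lower and 144 lay between. Higher loci included 1226609 to 1228846 on the plus strand, with a relative log2 ratio of 2.73 and median levels of 36.8 in SB1003 and 240 in DE442. The locus at 1973740 to 1979027 on the minus strand, within the second most complex DE442 unit, was at 2.64 over 24 transcripts. Within the most complex DE442 unit, the locus at 758331 to 765414 on the plus strand was at -0.11 over 175 transcripts. The smaller loci of that unit were at 0.16, 0.48 and 0.71. The highest median, 3.21 at 1584435 to 1584529 on the minus strand, ranged from 0.29 to 3.21 over its transcripts. Its median level in SB1003 was 4.69, near the lowest listed level of 3.01, and 42.6 in DE442. Among the lower loci, 1327354 to 1327447 on the plus strand was at -4.98 with median levels of 497 in SB1003 and 15.4 in DE442, and 3312614 to 3312752 on the plus strand was at -4.24. The number of such loci depended on the match, with 9 higher and 5 lower when both ends had to be identical, and 54 higher and 59 lower when 50 nt were allowed. The match also changes how many loci can hold 3 shared transcripts, since 2.08% and 43.6% of SB1003 transcripts were shared in these settings. The number of loci compared in them is not given, so these counts do not show whether the level differences themselves changed.

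**Figure D3:**
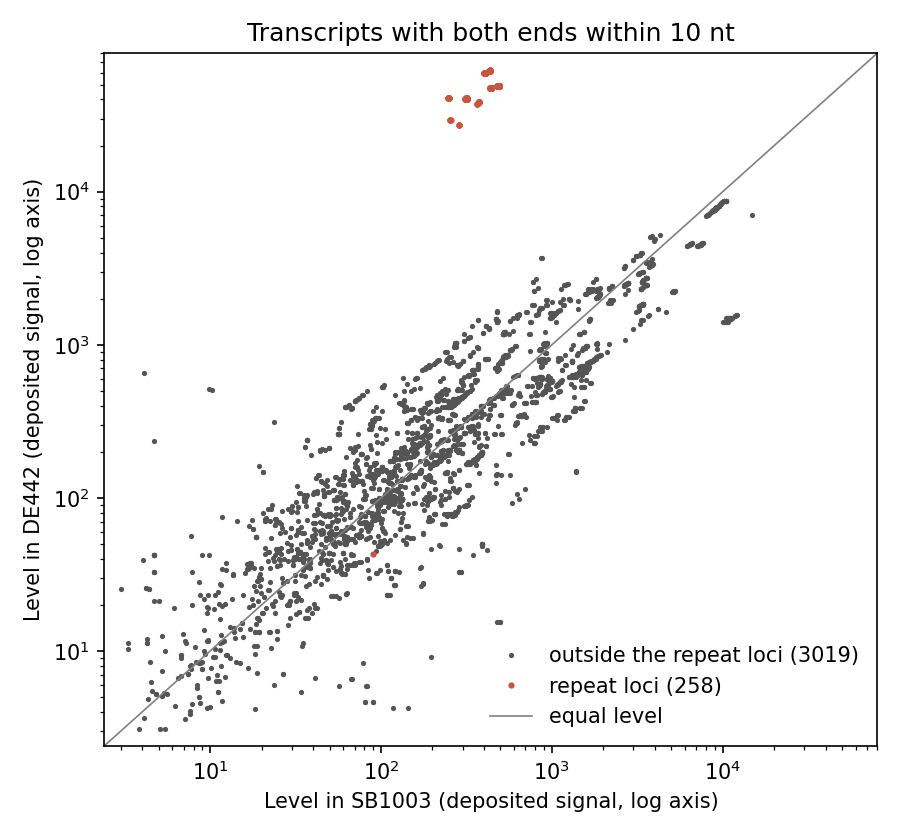
Level in DE442 (y axis) against level in SB1003 (x axis), both as deposited signal on log axes, for transcripts with both ends within 10 nt; grey points lie outside the repeat loci (3019), red points in them (258), and the line marks equal levels. Red points at the top lie far above the line, with a median log2 ratio of 6.75 over all 258.

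Some loci carried transcripts of identical length and level at places over 10 kb apart. A family of 4 lay at 159978 to 162141, 1003719 to 1009459 and 1513758 to 1519569 on the plus strand and 3580302 to 3582473 on the minus strand, and a pair at 3051913 to 3055455 on the plus strand and 2285527 to 2289872 on the minus strand. Such transcripts cannot be assigned to a copy. Over the 258 shared transcripts in these loci the level was 108-fold higher in DE442 (median log2 ratio 6.75). At the locus starting at 1003719 the median level of shared transcripts was 438 in SB1003 and 48961 in DE442. At the 2 loci of the family over 5 kb the shared transcripts all lay in the earlier part. In a later stretch, 1006333 to 1009459 and 1516431 to 1519425, the SB1003 level was 23782 and 24693. DE442 listed no transcript of that stretch alone. If the level is mean depth, its nested transcripts allowed at most 46050 and 41718 there, a log2 ratio of at most 0.95 and 0.76. In the pair the order was the opposite: the highest level was 129 in SB1003 and 57.6 in DE442. Next to 2 copies of the family, SB1003 alone listed transcripts at 162602 to 165731 on the plus strand, with a level up to 33425, and at 3576712 to 3579766 on the minus strand, with a level up to 33458.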

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

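Distances, the better-ranked part by log2 value, reciprocal overlap and transcripts with both ends listed were planned; all settings on joining, repeat loci, the 2 DE442 loci, the fraction, the 50-nt gap, level loci and depth steps were chosen after seeing the data. Planned settings left 5 values within the interval or within 1.5 times and moved 31, and added ones left 22 and moved 9. The values that planned settings left were shared DE442 TTSs in the better-ranked part, at 27.5%, and transcript 5' ends at TSSs. The latter could not move, because every transcript begins at a listed TSS and the match is 100% at any distance. The cause was not tested except where the wider or narrower distance itself sets the count.

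Shared TSSs in SB1003 were 21.2% at 0 nt, 43.5% at 10 nt, 51.5% at 25 nt, 47.8% in the better-ranked part and 33.3% after joining neighbours. In DE442 these were 16.0%, 39.1%, 46.5%, 41.9% and 26.9%. Shared TTSs in SB1003 were 6.74% at 0 nt, 24.4% at 5 nt, 41.3% at 25 nt, 49.7% at 50 nt and 29.0% in the better-ranked part. In DE442 they were 5.98%, 22.5%, 38.4% and 45.2% at those distances. Shared transcripts in SB1003 were 2.08% at 0 nt, 43.6% at 50 nt and 40.8% by reciprocal overlap of at least 90%, and in DE442 1.25%, 33.9% and 35.4%. Transcripts that ended at a TTS were 85.4% at 0 nt and 88.4% at 50 nt in SB1003, and 90.8% and 92.6% in DE442. In every one of these settings the shared percentage was higher in SB1003, which has the shorter lists.

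Requiring both ends to be listed left 1034 units in SB1003 and 1082 in DE442, with several TSSs and ends in 42.6% and 48.2%. With fraction 1.0 that percentage was 33.9% and 39.2%, and joining within 50 nt gave 30.5% in SB1003. Level loci more than 2-fold higher in DE442 numbered 9 with identical ends, and lower ones 5 with identical ends and 59 within 50 nt. The number of loci that can be compared changes with the match as well. A depth rise of at least 2-fold at DE442 TSSs went from 24.1% to 21.4% with every pair of flanks. The transcript ratio stayed above 1 in its 5 settings, from 1.38 without the 2 DE442 loci to 1.85 outside the repeat loci.

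No paired analysis was possible because the lists pool the libraries of a strain. Leaving out a replicate, upstream windows of other lengths, other gene coverage, gene lists and sequence at shared positions were not run for want of values per library or a matching annotation. Depth is unknown and limits which weak ends each list was able to hold.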

Other observations

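Of the tests below, those on neighbouring ends and on coverage at unshared TSSs were set before their values were seen, though related counts were known; all others, and the depth steps, were chosen afterwards. No biological explanation was tested, and the difference between the strains remains open for each pattern.

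Depth on both sides of an end was measurable for 674 of 4045 TSSs in SB1003 and 1018 of 5374 in DE442, and for 1299 of 2906 and 1446 of 3279 TTSs. A TSS needs an overlapping transcript from upstream for this, so first TSSs of units are not among them and the values do not describe all ends. The depths are derived from the levels and hold only if the level is mean depth. Downstream of the 674 SB1003 TSSs the median log2 change in depth was 0.45, and 31.6% had a rise of at least 2-fold. For 1018 DE442 TSSs these were 0.33 and 24.1%. Across 1299 SB1003 and 1446 DE442 TTSs the median change was -0.62 and -0.56. Depth moved against the type of the end at 32.8% of SB1003 and 34.7% of DE442 TSSs, and at 24.9% and 25.3% of TTSs. Ends of log2 size 2 or more had a 2-fold step in their direction more often: 71.4% (51.3 to 86.8, n = 28) of such SB1003 TSSs against 29.9% (26.4 to 33.6) of those under 2, and 70.0% (45.7 to 88.1, n = 20) against 23.1% (20.6 to 25.9) in DE442. For TTSs these were 69.6% (47.1 to 86.8, n = 23) against 33.2% (30.6 to 35.8) in SB1003 and 63.6% (45.1 to 79.6, n = 33) against 28.5% (26.2 to 31.0) in DE442. Shared SB1003 TSSs had a 2-fold rise in 42.2% (34.5 to 50.3, n = 161), and unshared ones in 28.3% (24.4 to 32.4, n = 513). DE442 TSSs went the same way, at 32.4% (24.8 to 40.8, n = 142) and 22.7% (20.0 to 25.6, n = 876). These intervals overlapped, which does not show that the percentages are equal.

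DE442 had 1.68 times as many transcripts as SB1003 from 1.33 times as many TSSs. A TSS began up to 33 transcripts in SB1003 and up to 50 in DE442, as many as its unit had ends. The transcript ratio is therefore not independent of how TSSs and ends are spread over units. Repeat loci do not account for this, since the ratio outside them was 1.85. Joining ends within 5 nt left a ratio of 1.49, so neighbouring ends called separately account for part of the excess at most. A deeper signal in DE442 would raise shared transcripts generally, and their median log2 ratio was -0.031, with quartiles of -0.61 and 0.69. Which libraries enter the level is not stated, so this describes the level of shared transcripts only and does not settle depth. Depth of the end libraries, which could add weak TSSs within long units and multiply combinations of ends, stays open.

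Within 5 nt, most TSSs of each strain had no counterpart in the other. Small shifts of the called position account for part of this at most, as the SB1003 TSSs with a DE442 TSS went from 38.5% within 5 nt to 51.5% within 25 nt. The shared percentage in SB1003 was 55.6 points higher over a log2 value of 4 than under 0.5, so weak calls that pass a threshold in 1 strain by chance are a candidate explanation. That difference was known when the explanation was chosen and is no separate test. By position in SB1003 units, first TSSs (median log2 value 1.54) were shared at 34.5%. Those 1 to 50 nt after (1.68) were shared at 59.1% and those further on (0.48) at 33.7%. The percentage thus did not follow the median log2 value across these classes. TSSs 1 to 50 nt after the first lie near another TSS by definition, so several can match the same DE442 TSS. Their percentage was not computed after joining neighbours, which left 33.3% of all SB1003 TSSs shared. SB1003 listed no transcript at 50.6% (48.9 to 52.3) of unshared DE442 TSSs, and DE442 none at 44.9% (43.0 to 46.9) of unshared SB1003 TSSs. The first value lies between the bounds set for untranscribed regions as the main or a minor source and decides neither. Every listed transcript begins at a listed TSS, so a region with no TSS call at or before it has none, whatever RNA is there. The comparison therefore cannot tell an untranscribed region from one without calls.

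Shared transcripts in the repeat loci were 108-fold higher in level in DE442 by the median, while at the pair starting at 3051913 and 2285527 the median level of all transcripts was higher in SB1003, at 69.4 and 83.9 against 43.3 and 48.4. A single factor for the whole library is excluded, as the median log2 ratio outside the repeats minus that inside was -6.78. Better recovery of the whole repeated RNA in DE442 was tested at the 2 loci over 5 kb, in the later stretch covered by an SB1003 transcript, with all DE442 depth after the earlier part put into it. The highest log2 ratio this allowed, minus that of the earlier part, was -5.73. If the level is mean depth, this argues against such recovery at these loci. That reading was checked only on transcripts under 150 nt. The bound rests on 1 nested DE442 transcript at the locus starting at 1003719 and 21 at that starting at 1513758. Both loci belong to the same repeat family, so they are not separate observations. A process acting on the earlier part, such as its loss in the SB1003 library, may be involved and was not tested.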
